A study of Rattus norvegicus with 4 samples.

How the data were processed

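Cultured olfactory ensheathing cells of rat olfactory mucosa and olfactory bulb were measured on 4 Agilent whole-genome rat arrays of 45018 features with probes of 60 bases. Per the labels' protocols, RNA was amplified by a global PCR of cDNA, 250 ng of cDNA per channel were labelled, and mucosa cells carried Cy5 and bulb cells Cy3. The amplification and labelling steps are not disclosed there, and PCR can change the ratio of transcripts. Per the labels, the 4 arrays are biological replicates, and per the design text the samples are paired. All 4 were on 1 slide and had 1 scan time, so neither was tested as a batch.

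Per the file headers, the scanner files were made with Agilent Feature Extraction 10.5.1.1, and the submitters' processing notes name version 9.1. The deposited spot and background signals are linear intensity values, without normalization. Per the file headers, the processed intensity signals were background-subtracted and dye-normalized by the scanner software, and the deposited ratio is the log10 of Cy5 over Cy3. The deposited value table of the series holds the same log10 ratios at all 45018 features of each array. Its scale, centring and direction are thereby known, and its column medians were 0, 0, 0 and 0.000422. It has 0 columns without a sample. Probe coordinates are those of the rn4 build, per the file headers; no annotation of exons or introns was used here.

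Mean signals and median local background were corrected with normexp at an offset of 50 and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control and outlier spots at weight 0. Outlier spots were left out, and spots of 1 probe were averaged. A probe was tested if it was well above background, in at least 0.5 of its spots, on at least 3 arrays in at least 1 channel. This left 36749 probes and removed 4263, and 42 probes lacked a ratio on some array. The probe of highest mean intensity stood for each gene name, which gave 31868 names, of which 11143 are gene symbols and the others accessions, clones or clusters. Gene names are those of the array design, without the endings for predicted and mapped genes. Of 41012 probes, 11140 were named through an accession, 1076 through a gene ID, 5112 through a symbol and 3424 through a synonym in a reference table of the GRCr8 assembly, used for names only, and 20260 kept the name of the file. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, with labels read through jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9.

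The log2 ratio of each array was the difference within a pair, and its mean was tested against 0 with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 6.36 degrees of freedom after moderation. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The 28 lists, 11 of cell type markers and 17 of functions, were fixed before the data were examined. So was the rule for named genes. It took the 8 largest positive and 8 largest negative ratios among called genes with a symbol and the same sign on all arrays. It also took up to 3 called members of largest absolute ratio per list (or the largest where 0 passed), and 16 genes of glia, matrix and trophic factors whatever their result. It named 88 genes, of which 80 were called, and some of these are not reported here.

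The fit was tested on simulated ratios for the 31868 names. Of 100 names changed by a log2 ratio of 1 it recovered 2%, and of 100 changed by 2 it recovered 83%, with 5 false calls, and it made 0 calls where nothing changed. Changes of 2-fold were therefore mostly missed in that simulation. It held far fewer changed names than the 2110 called here, and the adjustment is stricter with fewer. Its shares therefore do not measure recovery in the real data, where the smallest call was 1.85-fold. With the effects of the 2110 called genes the fit recovered 90.6% of them, and 5.63% of its calls were false. Those effects were the estimates of genes that had already passed, and the noise was independent between genes. The 90.6% is therefore high by design and does not measure recovery or false calls in the real data.

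Alternatives were no background subtraction, the processed signals, an offset of 16, median centring, the deposited ratio and value table, scale and Aquantile normalization between arrays, and no filter or a strict one. Others were saturated probes left out, outlier spots kept, the mean over probes, array weights, a trended robust variance, an unmoderated statistic, treat against 1.5-fold, unpaired channels, and each replicate left out. Names updated through the reference table and removal of the trend with probe GC content (loess, span 0.3) were added after seeing the data. Where signals, filter or names changed, the brightest probe was chosen anew, so another probe could stand for a gene.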

Results

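Olfactory ensheathing cells are glia that wrap the axons of olfactory sensory neurons on their way from the nose to the brain. Messenger RNA of such cells, cultured from the olfactory mucosa and from the olfactory bulb of male Fischer rats, was compared on 4 arrays. Each array held 1 of 4 biological replicates as a pair, with mucosa cells in the Cy5 channel and bulb cells in the Cy3 channel. The dyes had the same orientation on each array, so a dye effect and a tissue effect cannot be told apart by the design. The median spot signal lay between 567 and 842 in Cy5 and between 342 and 382 in Cy3. Between 82.8% and 91.1% of the spots of a channel were well above background. The number of arrays limits the precision of each value.

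The comparison asks which genes differ in expression between ensheathing cells of the 2 tissues. Grem1, a secreted antagonist of bone morphogenetic proteins, was 37.0-fold higher in mucosa cells (log2 ratio 5.21 ± 0.53, SD, n = 4), though only 2.24 ± 0.96 at a second probe. By the deposited ratio it had 2.50, where the probe was chosen anew and may be the second one. Col2a1, the main collagen of cartilage, Eln, which encodes elastin, and the transcription factor Pax3 were higher by 29.9-fold, 28.5-fold and 26.5-fold. Sst, which encodes the neuropeptide somatostatin, was 69.7-fold lower in mucosa cells (log2 ratio -6.12 ± 0.41, SD, n = 4), and the cytokine gene Il11 was 50.5-fold lower. Of 31868 gene names tested, 1031 were higher and 1079 lower in mucosa cells by limma with Benjamini-Hochberg adjustment, and 2047 of these differed at least 2-fold. The 4 arrays had the same sign for 33.6% of all gene names, where chance gives 12.5%, though a dye effect common to the arrays would also give shared signs. Between pairs of arrays the Pearson correlation of the ratios across genes lay between 0.35 and 0.54. Median centring in place of loess gave 1466 higher and 993 lower, or 59.6% higher against 48.9%.

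**Figure D1:**
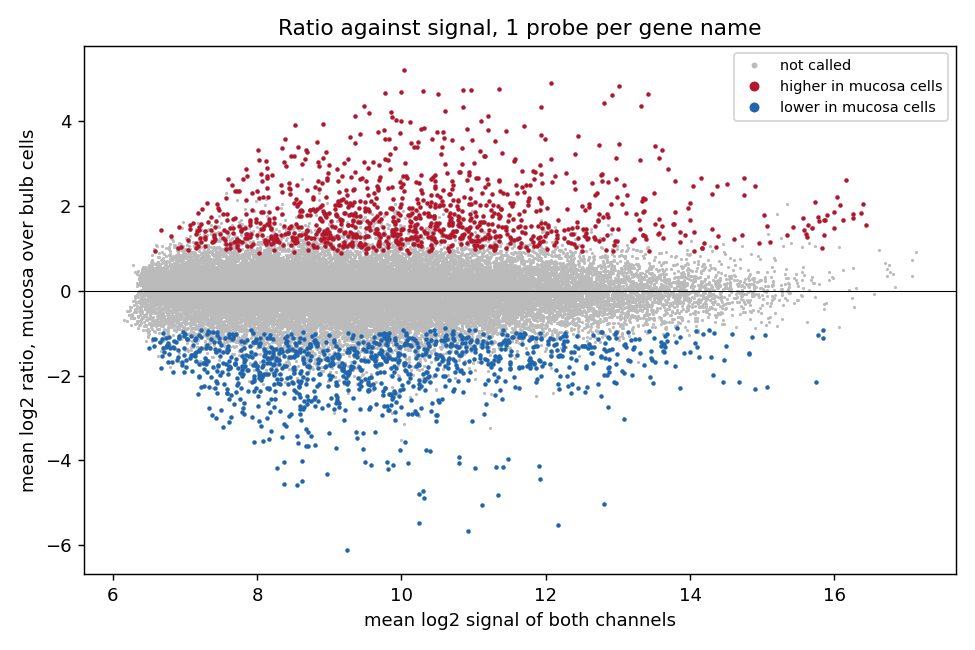
Mean log2 ratio of mucosa over bulb cells (vertical axis) against the mean log2 signal of both channels (horizontal axis), with 1 point for each of the 31868 gene names tested. The 1031 names higher and the 1079 names lower in mucosa cells are coloured, and both kinds occur over the range of signal.

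The 8 named genes of largest positive ratio were Grem1, Col2a1, Eln, Ccn4, Pax3, Eps8l1, Palmd and Thbs1, with adjusted p from 0.00107 to 0.00489. Ccn4 (Wisp1 on the array), a Wnt-induced matricellular protein, had a log2 ratio of 4.77 ± 0.42 (SD, n = 4), and Thbs1, the matrix glycoprotein thrombospondin 1, had 4.65 ± 0.25. Eps8l1, related to a substrate of the epidermal growth factor receptor, had 4.71 ± 0.55, and Palmd had 4.68 ± 1.23. Col2a1 had 4.90 ± 0.56, Eln 4.83 ± 0.61 and Pax3 4.73 ± 0.18. The Grem1 probe lies on chromosome 3, 99597425 to 99597483 of the rn4 build, per the file headers, and that of Pax3 on chromosome 9, 77509396 to 77509455. The second Grem1 probe lies on the same chromosome, from 99600383 to 99600442, and the deposited ratio gave Grem1 an adjusted p of 0.0452. The probe was chosen anew for the deposited ratio, so that value may be of the second probe. Second probes of Col2a1 and Pax3 also had smaller ratios, 3.51 ± 0.85 and 3.24 ± 0.26.

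Among the 8 of largest negative ratio were Sst, Il11, Ncan, Apod, Cilp, Atp1b2 and Cox6b2, with adjusted p from 0.00107 to 0.00615. Ncan (Cspg3 on the array), the proteoglycan neurocan of brain matrix, had a log2 ratio of -5.05 ± 0.74 (SD, n = 4), and the lipocalin gene Apod had -5.04 ± 0.88. Cilp, a cartilage matrix protein, had -4.83 ± 1.39 (-5.41 without replicate 2), Il11 -5.66 ± 0.81 and Cox6b2, a subunit of cytochrome c oxidase, -4.72 ± 0.75. Atp1b2, a pump subunit of glia, had -4.79 ± 0.73. Other probes had smaller ratios, -2.97 ± 1.25 for Cilp and -2.50 ± 0.19 and -2.43 ± 1.12 for Atp1b2. The Sst probe lies on chromosome 11, 79126027 to 79126086 of rn4 and was well above background on 2 of 4 mucosa arrays and on 4 of 4 bulb arrays, and its ratio was -7.92 by the deposited ratio. Of the 29 named genes with more than 1 tested probe, 1 had probes of different signs.

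**Figure D2:**
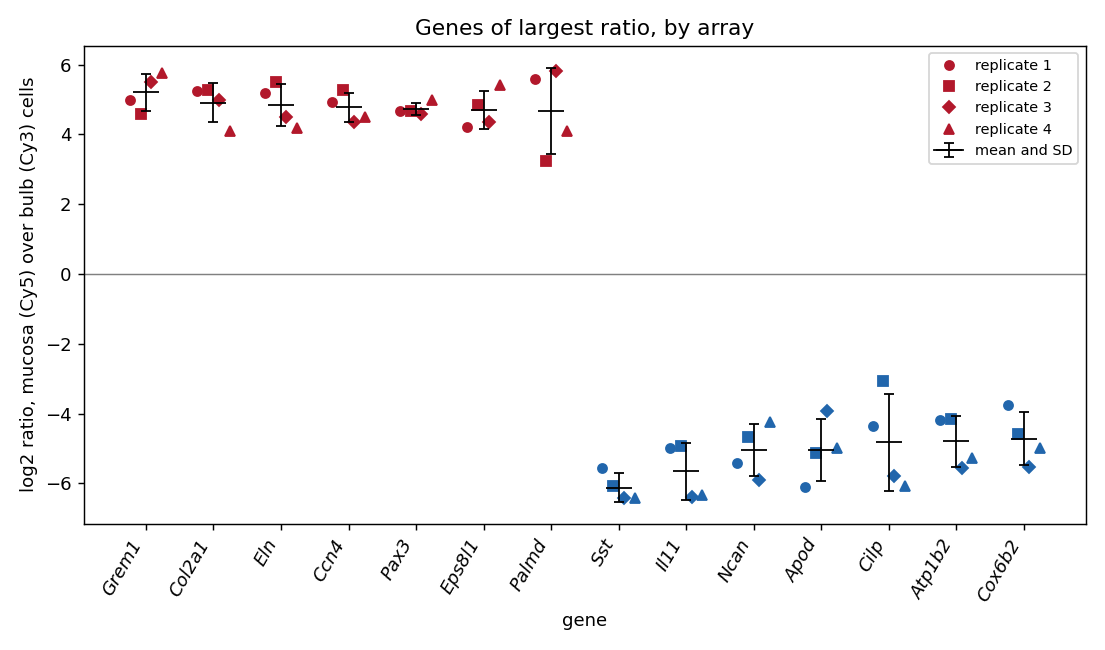
Log2 ratio of mucosa over bulb cells (vertical axis) of the 7 named genes of largest positive and the 7 of largest negative mean ratio (horizontal axis), each point 1 array and each bar the mean and SD of 4. Palmd and Cilp have the widest spread, with SDs of 1.23 and 1.39.

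Most called markers of ensheathing and Schwann glia were lower in mucosa cells, and most markers did not pass. The lipid-binding protein gene Fabp7 was 7.67-fold lower (log2 ratio -2.94 ± 0.49, SD, n = 4), the cadherin gene Cdh19 5.44-fold, and Sox10, the transcription factor of neural crest glia, 3.65-fold. S100b and the neurotrophin receptor gene Ngfr had log2 ratios of -1.49 ± 0.13 and -1.27 ± 0.23. Gldn, the gliomedin gene, was the 1 called member in the other direction, at 1.87 ± 0.58. The list of ensheathing and Schwann glia had 1 higher and 6 lower of 22 tested members (1 and 8 adjusted over the list alone), with camera adjusted p = 0.0420 toward lower ratios, and adjusted p = 0.352 with an estimated correlation. This list was called in 9 of 18 distinct alternative settings, and not without replicate 3 or 4 (adjusted p = 0.103 and 0.0573) or with the GC trend removed (0.0597). The following calls were also lost with 1 array left out: Ngfr without each of the 4 arrays in turn (highest adjusted p = 0.107); Cdh19 without replicate 1, 3 or 4 (highest adjusted p = 0.0708); Sox10 without replicate 1, 2 or 4 (highest adjusted p = 0.0753); S100b and Gldn without replicate 1 or 2 (highest adjusted p = 0.0632 and 0.0778).

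Most called markers of central glia and neurons were lower in mucosa cells. Camera called none of these lists, while fry called astrocytes, oligodendrocyte lineage and myelin lower (adjusted p = 0.00853, 0.0270 and 0.0289). Gfap, the intermediate filament of astrocytes, was 2.71-fold lower (log2 ratio -1.44 ± 0.26, SD, n = 4), and the glutamate transporter gene Slc1a3, well above background on 3 mucosa arrays, was 3.61-fold lower, with -2.90 and no call by the deposited ratio (adjusted p = 0.0764). A second Slc1a3 probe had a smaller ratio, -0.81 ± 0.26. Astrocyte markers had 0 higher and 4 lower of 18 tested members (1 and 4 adjusted over the list alone), with camera adjusted p = 0.602 toward lower ratios, and adjusted p = 0.779 with an estimated correlation. The median of that list was 0.24 and its mean -0.30, so they differ in sign. Camera, which sets a list against the other genes, pointed the same way as the mean. Oligodendrocyte lineage markers had 1 higher and 4 lower of 15 tested members (1 and 4 adjusted over the list alone), with camera adjusted p = 0.299 toward lower ratios, and adjusted p = 0.580 with an estimated correlation. The proteoglycan gene Cspg4, also a pericyte marker, was higher at 2.65 ± 0.31, and Cldn11, a tight junction gene, was lower at -2.67 ± 1.40. Myelin genes had 0 higher and 4 lower of 14 tested members (0 and 4 adjusted over the list alone), with camera adjusted p = 0.189 toward lower ratios, and adjusted p = 0.527 with an estimated correlation. Mbp was lower at -1.49 ± 0.44. These lists share genes, so their counts are not separate evidence: 10 of 15 oligodendrocyte and 10 of 14 myelin members were also in another list. Cldn11 and Mbp counted in both. Sox10 and Fabp7, given above for ensheathing glia, were also among the called oligodendrocyte and astrocyte members. Neuronal markers had 0 higher and 3 lower of 19 tested members (1 and 3 adjusted over the list alone), with camera adjusted p = 0.517 toward lower ratios, and adjusted p = 0.823 with an estimated correlation. The 3 lower ones were the neurofilament genes Nefm (Nef3 on the array), Nefl and Nefh, at -3.06 ± 0.69, -2.78 ± 0.24 and -1.54 ± 0.44. The neuronal list had a median of 0.032 and a mean of -0.34. Arrays left out singly ended these calls: Gfap, Slc1a3, Cldn11 and Mbp without each of the 4 arrays in turn (highest adjusted p = 0.0710, 0.108, 0.118 and 0.0740); Nefh without replicate 1, 2 or 4 (highest adjusted p = 0.0809).

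Most called genes of fibroblasts, of mural cells and of fibrillar matrix were higher in mucosa cells. Mfap5, a component of elastic microfibrils, was 15.9-fold higher (log2 ratio 3.99 ± 1.16, SD, n = 4), with 2.41 ± 0.62 at a second probe, and the surface glycoprotein gene Thy1, used to mark fibroblasts, 14.9-fold higher. The actin-binding protein genes Cnn1 and Tagln of smooth muscle were higher at 2.70 ± 0.71 and 2.46 ± 0.24. Fbln1, a fibroblast matrix gene, and Dcn, the collagen-binding proteoglycan decorin, went the other way, at -4.15 ± 0.62 and -2.01 ± 0.95. Fibroblast markers had 9 higher and 2 lower of 28 tested members (12 and 4 adjusted over the list alone), with camera adjusted p = 0.0181 toward higher ratios, and adjusted p = 0.603 with an estimated correlation, and fry did not call the list (adjusted p = 0.0618). Smooth muscle and pericyte markers had 7 higher and 1 lower of 15 tested members (8 and 2 adjusted over the list alone), with camera adjusted p = 0.00827 toward higher ratios, and adjusted p = 0.352 with an estimated correlation. Fibrillar collagen and fibre assembly genes, led by Col2a1 and Col1a2 (2.27 ± 0.45), had 6 higher and 1 lower of 24 tested members (10 and 3 adjusted over the list alone), with camera adjusted p = 0.0180 toward higher ratios, and adjusted p = 0.352 with an estimated correlation. Cartilage and bone markers had 3 higher and 0 lower of 18 tested members (4 and 0 adjusted over the list alone), with camera adjusted p = 0.0180 toward higher ratios, and adjusted p = 0.352 with an estimated correlation, and their called members were Col2a1, the cartilage matrix gene Comp (3.59 ± 1.01) and Col9a1 (1.21 ± 0.28). The lists share genes: 13 of 28 fibroblast members were also in another list. Without replicate 1 the fibroblast list was not called (adjusted p = 0.0786). Calls lost with 1 array left out were Col9a1 without each of the 4 arrays in turn (highest adjusted p = 0.113); Dcn without replicate 2, 3 or 4 (highest adjusted p = 0.117).

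Other matrix genes changed in both directions. Mmp12, a metalloelastase, was higher at 3.59 ± 0.91 (SD, n = 4) and well above background on 1 of 4 bulb arrays. Its size depends on the processing, with 6.26 by the deposited ratio, which differs in both background and dye normalization. The urokinase gene Plau and the gelatinase gene Mmp2 were higher at 2.57 ± 0.80 and 2.56 ± 0.28. Timp2, an inhibitor of such enzymes, was higher at 2.00 ± 0.60, while Timp1 had 0.59 ± 0.31 (adjusted p = 0.170). The fibronectin gene Fn1 had 1.06 ± 0.50 without passing (adjusted p = 0.0659). Proteases and inhibitors had 6 higher and 4 lower of 30 tested members (7 and 4 adjusted over the list alone), with camera adjusted p = 0.710 toward higher ratios, and adjusted p = 0.823 with an estimated correlation, a median of -0.046 and a mean of 0.19. Basement membrane genes had 1 higher and 3 lower of 19 tested members (4 and 5 adjusted over the list alone), with camera adjusted p = 0.602 toward lower ratios, and adjusted p = 0.779 with an estimated correlation. Among them the laminin gene Lama5 was higher at 1.29 ± 0.41, and the laminin gene Lamc1 and the nidogen gene Nid2 were lower at -1.23 ± 0.35 and -1.13 ± 0.42. With 1 array left out, the calls lost were Lama5, Lamc1 and Nid2 without each of the 4 arrays in turn (highest adjusted p = 0.0973, 0.112 and 0.177); Timp2 without replicate 1 or 2 (highest adjusted p = 0.0713).

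Transcription factors of body position and signalling genes of the Wnt and BMP pathways had calls in both directions. Pax3 and Eya4, a factor of cranial placodes, were higher in mucosa cells at 4.73 ± 0.18 and 3.01 ± 0.61 (SD, n = 4; 1.81 ± 0.91 at a second Eya4 probe), and the zinc finger gene Zic1 was 20.1-fold lower at -4.33 ± 0.15. Positional transcription factors had 7 higher and 2 lower of 33 tested members (12 and 3 adjusted over the list alone), with camera adjusted p = 0.0215 toward higher ratios, and adjusted p = 0.527 with an estimated correlation, and the list was not called with the GC trend removed (adjusted p = 0.0609). Wnt and BMP genes had 6 higher and 1 lower of 40 tested members (10 and 3 adjusted over the list alone), with camera adjusted p = 0.0215 toward higher ratios, and adjusted p = 0.352 with an estimated correlation. Grem1, the ligand gene Bmp3 (2.31 ± 0.75, well above background on 3 bulb arrays, 4.18 by the deposited ratio) and the Wnt regulator gene Dkk3 (2.01 ± 0.85) were the called members of largest ratio. The Wnt and BMP list was not called without replicate 1 or 2 (adjusted p = 0.0513 and 0.0505), with the strict filter (0.137) or with the GC trend removed (0.0583). Array by array, the calls that ended were Bmp3 without replicate 1, 2 or 4 (highest adjusted p = 0.0710); Dkk3 without replicate 1, 2 or 3 (highest adjusted p = 0.107).

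Among growth factors, Angpt1, a ligand of an endothelial receptor, and the fibroblast growth factor gene Fgf7 were higher in mucosa cells at 3.64 ± 0.87 and 3.31 ± 0.44 (SD, n = 4). Ptn, a heparin-binding neurite outgrowth factor, was 15.1-fold lower, and the neurotrophin gene Bdnf 7.05-fold lower, at -2.82 ± 0.86. Gdnf did not pass, at 0.12 ± 0.17 (adjusted p = 0.749). Growth and neurotrophic factors had 6 higher and 2 lower of 38 tested members (8 and 6 adjusted over the list alone), with camera adjusted p = 0.471 toward higher ratios, and adjusted p = 0.603 with an estimated correlation, while fry called the list higher (adjusted p = 0.00789). Axon guidance genes had 7 higher and 4 lower of 46 tested members (11 and 6 adjusted over the list alone), with camera adjusted p = 0.616 toward higher ratios, and adjusted p = 0.823 with an estimated correlation, and the semaphorin genes Sema3d and Sema3f and the ephrin gene Efna5 were the called members of largest ratio, at 2.45 ± 0.059, 2.32 ± 0.86 and 2.17 ± 0.26. The Sema3f call was lost without replicate 2 or 4 (highest adjusted p = 0.0614).

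Most called adhesion molecules of neural cells and proteoglycans of brain matrix were lower in mucosa cells. The integrin gene Itgb8 was 5.90-fold lower (log2 ratio -2.56 ± 0.22, SD, n = 4) and Chl1, a relative of the adhesion molecule L1, 4.53-fold lower, whereas the cadherin gene Cdh13 was 11.4-fold higher (another probe had 1.57 ± 0.48). Neural adhesion and neurite outgrowth genes had 1 higher and 8 lower of 29 tested members (1 and 8 adjusted over the list alone), with camera adjusted p = 0.0180 toward lower ratios, and adjusted p = 0.427 with an estimated correlation. This list was not called without replicate 1 (adjusted p = 0.0582). Growth-inhibitory proteoglycans and myelin inhibitors had 1 higher and 5 lower of 19 tested members (3 and 8 adjusted over the list alone), with camera adjusted p = 0.0245 toward lower ratios, and adjusted p = 0.352 with an estimated correlation. Ncan and the brevican gene Bcan (-3.44 ± 0.60) were lower and Cspg4 higher. The Bcan probe was well above background on 2 mucosa arrays, and 2 other probes of the gene had ratios of -0.68 ± 0.48 and -1.43 ± 0.88. With a normexp offset of 16 the brightest probe was chosen anew, and the Bcan ratio was -0.76 (adjusted p = 0.169). That value lies near the -0.68 of another probe, so it may reflect a change of probe and not of offset. That list was not called with the offset of 16 or with the deposited ratios (adjusted p = 0.0660 and 0.0823).

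The called complement genes were lower in mucosa cells, with C4a, C3 and the protease gene Masp1 at -4.15 ± 0.86, -2.87 ± 1.02 and -2.65 ± 0.74 (SD, n = 4). The list had 0 higher and 5 lower of 19 tested members (1 and 7 adjusted over the list alone), with camera adjusted p = 0.0217 toward lower ratios, and adjusted p = 0.576 with an estimated correlation, and was not called without replicate 3 (adjusted p = 0.0971) or with array weights (0.0563), nor by fry (adjusted p = 0.0700). Cytokine and chemokine genes had 1 higher and 4 lower of 29 tested members (2 and 6 adjusted over the list alone), with camera adjusted p = 0.754 toward lower ratios, and adjusted p = 0.876 with an estimated correlation. Il11 and the fractalkine gene Cx3cl1 (-1.62 ± 0.48, but -0.40 ± 1.21 at a second probe) were lower. The prostaglandin synthase gene Ptges was higher at 2.03 ± 0.55. That list had a median of 0.19 and a mean of -0.28. The MHC class II genes RT1-Da and RT1-Bb and the gene Cd74 of their invariant chain were called higher at 3.27 ± 1.02, 2.81 ± 0.65 and 3.10 ± 0.82, and other probes of RT1-Da and RT1-Bb had 1.49 ± 0.64 and 0.62 ± 0.34. The deposited ratio gave RT1-Da 4.52. RT1 genes form a family of close relatives, and probes of one can bind transcripts of another. The interferon and antigen presentation list had 4 higher and 1 lower of 33 tested members (5 and 5 adjusted over the list alone), with camera adjusted p = 0.602 toward lower ratios, and adjusted p = 0.823 with an estimated correlation. Arrays left out singly ended these calls: Cx3cl1 without replicate 1, 2 or 3 (highest adjusted p = 0.0890); C3, Masp1 and RT1-Da without replicate 1 (highest adjusted p = 0.0733, 0.0547 and 0.0580); Ptges without replicate 2 (highest adjusted p = 0.0640).

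Lists of other cell types were not called by camera, and fry called the meningeal list lower (adjusted p = 0.00853). Each of these lists held a larger share of called genes than the 6.62% of all gene names, the epithelial list with only 1 called gene. Microglia and macrophage markers had 2 higher and 0 lower of 18 tested members (2 and 1 adjusted over the list alone), with camera adjusted p = 0.754 toward higher ratios, and adjusted p = 0.927 with an estimated correlation, a median of -0.19 and a mean of 0.076. Their called members were Cd74 and the lysozyme gene Lyz2 (Lyz on the array, 2.87 ± 1.73, SD, n = 4, and 3.50 without replicate 3). Endothelial markers had 2 higher and 1 lower of 16 tested members (3 and 1 adjusted over the list alone), with camera adjusted p = 0.163 toward higher ratios, and adjusted p = 0.779 with an estimated correlation. Eng, an accessory receptor of transforming growth factor beta, and Tek were higher at 2.05 ± 0.49 and 1.51 ± 0.79, and the cadherin gene Cdh5 was lower at -1.57 ± 0.67. Epithelial markers had 0 higher and 1 lower of 11 tested members (0 and 1 adjusted over the list alone), with camera adjusted p = 0.602 toward higher ratios, and adjusted p = 0.823 with an estimated correlation, while fry pointed to lower ratios (adjusted p = 0.967), and the 1 called gene was Cdh1, E-cadherin, at -2.40 ± 0.37 (-3.67 by the deposited ratio). Meningeal markers had 1 higher and 4 lower of 14 tested members (2 and 5 adjusted over the list alone), with camera adjusted p = 0.112 toward lower ratios, and adjusted p = 0.427 with an estimated correlation. Zic1, the transcription factor gene Tbx18 (-2.77 ± 0.53) and Cldn11 were lower in mucosa cells. Calls lost with 1 array left out were Tek, Cdh5 and Cldn11 without each of the 4 arrays in turn (highest adjusted p = 0.150, 0.0984 and 0.118); Lyz2 without replicate 1, 2 or 4 (highest adjusted p = 0.155); Eng without replicate 1 or 2 (highest adjusted p = 0.0567).

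Lists of general cell functions had 0 or few calls by limma. Cell cycle genes had 0 calls among 36 tested members, against 1 at an unadjusted p under 0.05, with camera adjusted p = 0.432 toward lower ratios, and adjusted p = 0.741 with an estimated correlation. The member of largest ratio was the checkpoint kinase gene Bub1, at -0.92 ± 0.38 (adjusted p = 0.0702), which was well above background on 2 mucosa arrays and passed with a normexp offset of 16 (-1.40, adjusted p = 0.0404) and with median centring (-1.24, adjusted p = 0.0258). By the deposited ratio it had -2.35 without passing (adjusted p = 0.0521). Cholesterol synthesis genes had 0 calls among 22, against 1 higher and 2 lower at an unadjusted p under 0.05, with camera adjusted p = 0.754 toward lower ratios, and adjusted p = 0.876 with an estimated correlation, and Pmvk had 1.04 ± 0.51 (adjusted p = 0.0698). Cytosolic ribosomal protein genes had 0 calls among 60, with 0 at an unadjusted p under 0.05, and Rps3 had -0.53 ± 0.45 (adjusted p = 0.250). Their list had camera adjusted p = 0.990 toward higher ratios, and adjusted p = 0.997 with an estimated correlation, with a median of -0.0090 and a mean of -0.0020, opposite in sign to the test, and was called higher with median centring in place of loess (adjusted p = 0.00309). These 3 lists had 0 calls also by the unmoderated statistic, by treat and by the trended robust fit, which is no added evidence. All calls of treat and of the trended robust fit were among the 2110 main calls, and the unmoderated statistic made only 72 calls. Immediate early genes had 2 higher and 1 lower of 23 tested members (4 and 1 adjusted over the list alone), with camera adjusted p = 0.149 toward higher ratios, and adjusted p = 0.823 with an estimated correlation. Nr4a3 was higher at 1.54 ± 0.67 (but 0.76 ± 0.97 and 0.45 ± 0.30 at its other probes) and Klf2 at 1.42 ± 0.57. Fosl2 was lower at -1.39 ± 0.31. That list was called higher without replicate 3 or 4 (adjusted p = 0.0351 and 0.0384), with median centring (adjusted p = 0.0278) and with array weights (adjusted p = 0.0450). With 1 array left out, the calls lost were Fosl2 without each of the 4 arrays in turn (highest adjusted p = 0.0745); Nr4a3 and Klf2 without replicate 1, 2 or 3 (highest adjusted p = 0.123 and 0.134).

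**Figure D3:**
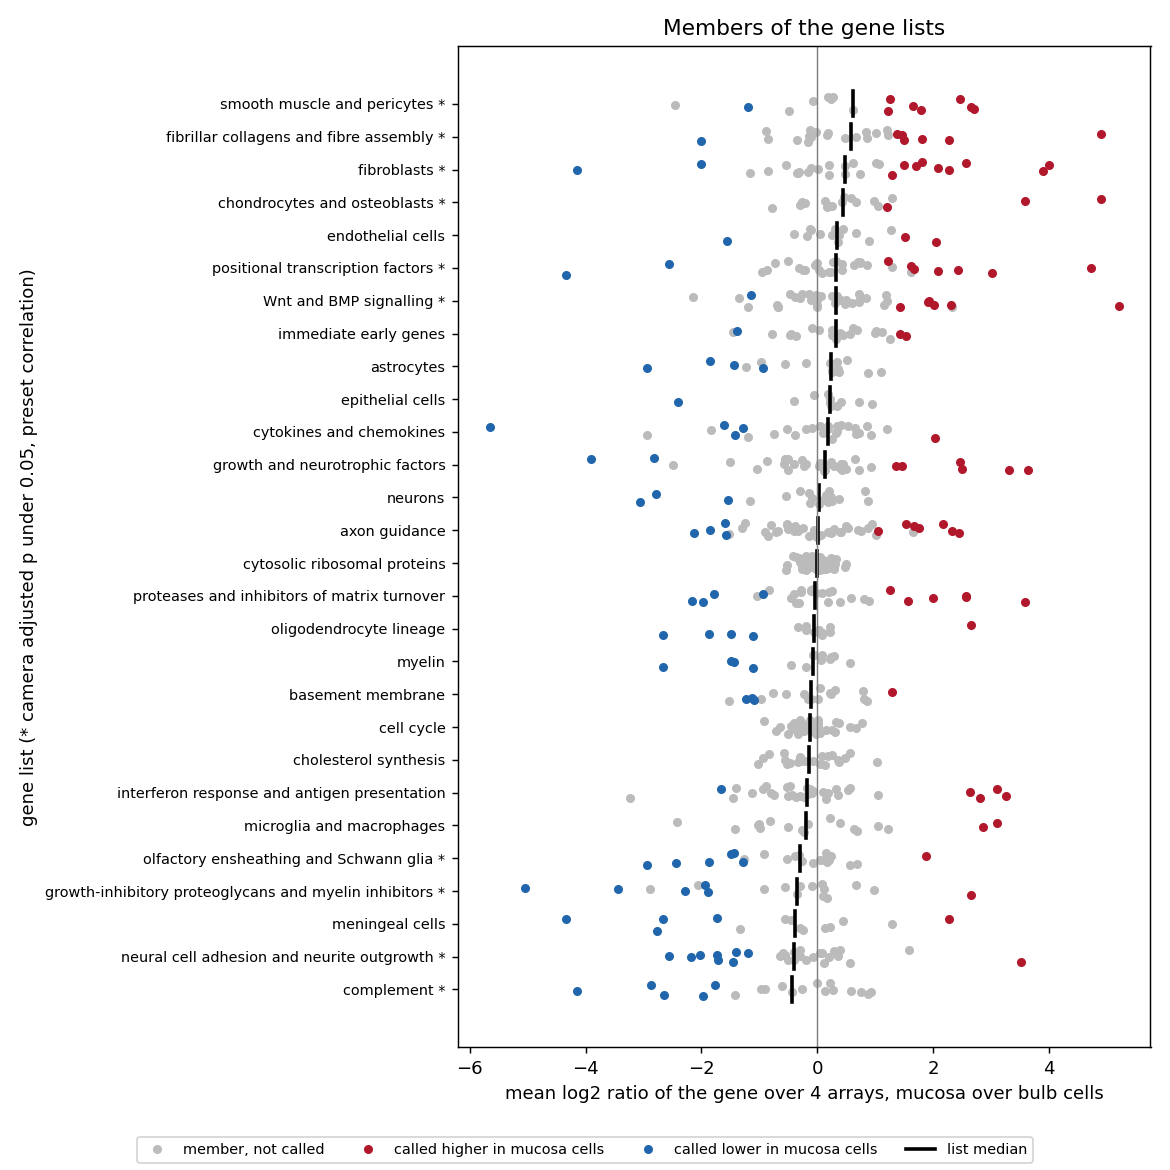
Mean log2 ratio of mucosa over bulb cells (horizontal axis) of each tested member of the 28 gene lists (vertical axis), with called members coloured and the list median as a bar. Smooth muscle and pericyte markers have the highest median, 0.62, and complement genes the lowest, -0.45; stars mark the 10 lists called with the preset correlation, 6 higher and 4 lower.

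Of the 28 lists, 0 were called with an estimated correlation, where 3 had an unadjusted p under 0.05, and 13 were called by fry, which does not set a list against other genes. The count of called genes fell when 1 array was left out, to between 282 and 539 higher and between 263 and 522 lower.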

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

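The count of array orientations and the tests of cell shares were chosen after the results they measure were seen, and the GC correction was added after the called genes were seen. Among 88 named genes, 5 (5.68%) had 1 array far from the other 3, where chance gives about 5%. Thbs1 had a log2 ratio of 5.03 on the array of replicate 2, against 4.51 to 4.53 on the others. Thy1 had 2.83 on replicate 4, against 4.14 to 4.31. Efna5 had 1.79 on replicate 1, against 2.26 to 2.35. Rps3 had -1.21 on replicate 3, against -0.35 to -0.28. Sox10 had -1.04 on replicate 3, against -2.15 to -2.14.

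Of 43 control probes of plant or spike-in type, 29 were above background in both dyes on all 4 arrays and the others were not. Among these 29, which that choice sets above the negative controls, the median Cy3 signal was 159 for 22 probes of the AT class and 140 for 7 of the E1A class, against 21.4 for the negative controls. Their log2 ratios after normalization lay between -0.10 and 0.98.

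The pattern of 2110 called genes was set against technical explanations. A dye effect of single probes is argued against by 275 called genes with a second, non-overlapping probe, of which 92.4% (exact 95% interval 88.6 to 95.2) had the same sign at that probe, with a smaller median log2 size (1.14 against 1.62). A trend with probe GC content is argued against as the whole cause by the 91.0% of calls kept in the same direction with the trend removed, though 3 of the 10 list calls were lost. A dye effect shared by all probes of a gene and the tissue cannot be told apart, since 0 arrays had reversed dyes. The 8 orientations of the 4 ratios are too few for a share under 0.05: the real one called 2110 genes and the highest other 0, so 1 orientation reached the real count.

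The higher ratios of most called fibroblast, mural and cartilage genes in mucosa cells may come from a larger share of fibroblasts in those cultures. Of 12 abundant fibroblast transcripts, 4 were called higher and 1, Dcn, lower, with a median log2 ratio of 0.61, so neither a rise of most nor its absence was shown. A smaller share of glia would raise markers of other types alike and lower those of ensheathing glia, of which 6 of 22 were called lower and 1 higher, so it stays open for that list too. The fibroblast and meningeal medians were 0.48 and -0.38, a difference of 0.86 (2-sided permutation p = 0.0587), which does not show that they moved alike, a reading set after that value was seen. A difference in expression between the glia of the 2 tissues stays open and was not tested.

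The lower ratios of the 4 called astrocyte markers, in a list of 18 with a median of 0.24 that fry but not camera called, may come from astrocytes in the bulb cultures. Of 12 transcripts taken as abundant in astrocytes, Gfap and Slc1a3 were called lower and 0 higher (2 of 12 called by limma), with a median of -0.54, which leaves this open. They overlap the marker list and so are no separate test. Some were dim here, such as Aqp4 with log2 signals of 6.96 in mucosa and 6.62 in bulb cells. The called Gfap and Slc1a3 had 7.45 and 7.08 in mucosa and 8.89 and 8.93 in bulb cells. These lie below the signals of each of the abundant fibroblast transcripts. Ensheathing glia themselves express some astrocyte markers, Fabp7 among them, and a tissue difference within these glia was not tested.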

How the results depend on the processing

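Leaving out 1 array gave between 282 and 539 genes higher, between 263 and 522 lower, and between 562 and 1061 changed at least 2-fold, with fewer arrays as part of the cause. The scanner software's processed signals, its deposited ratio and the value table each gave 694 lower. The trended robust variance gave 568 higher, 330 lower and 898 at least 2-fold. The unmoderated statistic gave 40, 32 and 63, and treat against 1.5-fold, a stricter hypothesis, gave 326, 279 and 605. Channels compared without pairing (no replicate block) gave 1740 higher and 1743 lower. Apart from treat, the cause was not tested. The other settings kept these counts within 1.5 times the main ones. The number of lists called was 0 with an estimated correlation and within 1.5 times 10 in the other settings run. Over 18 distinct settings each of the 10 called lists kept its direction, as did most lists that were not called. Smooth muscle, fibrillar collagen and cartilage lists were called in 18, Wnt and BMP genes in 14 and ensheathing glia in 9.

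Of 80 called named genes, 1 changed its sign in some setting, to 1.71 with the strict filter. Gdnf, not called, turned to -0.12 with the GC trend removed, an alternative chosen after seeing the data, as were updated names, which kept 2107 of 2110 calls. Sizes also moved. The ratio furthest from 0 over the settings was 4.58 for Angpt1, 5.63 for Palmd, 5.38 for Eps8l1 and -5.15 for Zic1. The main ratios of these were 3.64, 4.68, 4.71 and -4.33. Without any 1 array 47 of the 80 calls held and 33 were lost at least once. Leaving out saturated probes removed 0 names and tests nothing, Aquantile leaves the ratios as they are, and a slide or scan block could not be fitted. The unmoderated statistic and treat have no counterpart for lists. Dim channels limit large ratios: Sst and Bcan were well above background on 2 of 4 mucosa arrays.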

Other observations

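The gene groups here were chosen after seeing the data, so their tests describe these arrays and are no independent evidence. Matricellular proteins, secreted proteins that bind matrix and receptors, had 8 of 18 tested members higher and 3 lower in mucosa cells (camera adjusted p = 0.00106 over 6 such groups, and adjusted p = 0.162 with an estimated correlation). Ccn2, Ccn3 and Ccn5 were higher by 5.66-fold, 4.85-fold and 4.57-fold, with log2 ratios of 2.50 ± 0.078, 2.28 ± 0.32 and 2.19 ± 0.15 (SD, n = 4, limma adjusted p = 0.00266, 0.00460 and 0.00393). Thbs4, Tnc and Sparcl1 were lower at -2.48 ± 1.13, -2.28 ± 0.46 and -2.83 ± 0.32. Sparc had 0.0061 ± 0.025 (adjusted p = 0.988). Elastic fibre genes went both ways, with 5 of 17 higher and 2 lower (camera adjusted p = 0.0741, and adjusted p = 0.337 with an estimated correlation). Besides Eln and Mfap5, Ltbp2 and Fbln5 were higher at 3.43 ± 0.46 and 3.18 ± 0.38, and Efemp1 was lower at -3.04 ± 0.64.

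Integrins had 4 of 16 members higher and 2 lower (camera adjusted p = 0.0779, and adjusted p = 0.337 with an estimated correlation), with Itga11 and Itga8 at 3.55 ± 0.32 and 3.22 ± 0.51 (SD, n = 4). Of 17 neuropeptide and granin genes, 4 were lower and 0 higher by limma (camera adjusted p = 0.0741, and adjusted p = 0.337 with an estimated correlation). Besides Sst, Calcb and Scg3 were lower at -4.01 ± 0.38 and -3.34 ± 0.90, and Trh, not well above background on the 4 mucosa arrays, was at least 2.79-fold lower (adjusted p = 0.0151). That bound sets the bulb mean against the lowest signal well above background, after loess and Aquantile, and is open to dye bias. Genes of insulin-like growth factor binding had 1 of 11 higher and 1 lower (camera adjusted p = 0.606, and adjusted p = 0.626 with an estimated correlation).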
